A study of Mus musculus with 6 samples.

How the data were processed

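The data are droplet single-cell RNA-seq libraries (10x Chromium 3′ v2) of mouse tissue. They comprise 5 libraries of XX gonad from ICR embryos at embryonic days 10.5, 11.5, 12.5, 13.5 and 14.5 (E10.5 to E14.5), and 1 library of gonad somatic cells made from embryonic stem cells and harvested at culture day 6 (Induced D6, 129svj x C57BL/6J). Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 3.0.2 on the mm10 build. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, and the cell calling settings are not given in the sources used here. The barcodes analysed were those the authors deposited. Gene coordinates were taken from GENCODE vM21 (GRCm38), matched on the Ensembl identifier, which found 30934 of the 31053 listed genes.

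Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublet scores were computed with Scrublet (in scanpy 1.11.5). Its automatic threshold called 0.0160% of E10.5 cells, under the 0.5% set as the least believable rate. The highest-scored cells were therefore removed in every library up to the expected rate, 0.8% per 1000 cells recovered. Doublets between cells of the same type cannot be found this way. Each library was clustered on its own: counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used, with random seed 0.

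Clusters were named from 23 sets of cell type markers. A marker counted for a cluster when its CPM (with 10 added) was at least 1.5 times the mean of the library's other clusters and at least 10% of the cluster's cells held it. A cluster took the name of the set with the largest share of its markers counted, if these were at least 3 markers and 33.3% of the set. It stayed unnamed where its 10 leading genes (at 50 CPM or more) held more markers of another class than of its own, or held markers of a class within a margin of 0.2 of the best, or where its depth was low and no marker led it. Clusters within that margin between supporting lineage and coelomic epithelium, or between germ cell and pluripotent stem cell, carry both names. These scoring thresholds were set after the data were seen, while the marker sets were fixed earlier. Names are therefore written as "-like" and rest on marker genes alone. The share of unnamed clusters is given per library. Gonadal somatic cells are the sum of the supporting-lineage-like, coelomic-epithelium-like and stroma-like classes and the clusters that carry both of the first 2 names. The gonadal-epithelium-like class joins the supporting-lineage-like and coelomic-epithelium-like clusters and the clusters that carry both names.

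With 1 library per group there are no biological replicates, so no test, p-value or standard error was computed. Shares of cells carry exact Clopper-Pearson 95% intervals, and for a share of 0 the share that 3 cells would make is given as the one allowed. UMI counts were summed over the cells of a class and expressed as CPM (counts scaled to a total of 1e6 per class) with exact Poisson intervals. Ratios between class sums carry exact conditional binomial 95% intervals. All of these cover counting error only. A gene at 0 counts was set to a floor of 3 counts over the class, and its ratio is then a bound. Genes at least 4-fold higher or lower were counted among those with at least 50 CPM in either class sum, with the class's own markers left out. The share of cells with a UMI was taken after thinning each cell to 3000 UMIs, leaving out cells below that depth. Correlations across genes used log2(CPM + 10) and genes with at least 10 CPM in at least 1 class sum. Genes are not independent replicates, and no p was attached.

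The genes named in the text follow a rule fixed before the data were examined, as were the main settings, the marker sets and the alternative settings, apart from the departures and additions given below. For each comparison the rule takes the 10 largest ratios in each direction among genes at 50 CPM or more. It leaves out class markers, mitochondrial, ribosomal protein and haemoglobin genes and clone-type names. It adds the members of each gene list with the largest ratios, and 27 key genes always. Some genes that meet the rule are not reported here. The 22 lists are gonadal primordium transcription factors, pregranulosa, Sertoli, steroidogenesis, Wnt/beta-catenin targets, Hedgehog targets, BMP targets, retinoic acid metabolism and targets, FGF/ERK targets, S phase, G2/M phase, glycolysis and hypoxia, cholesterol synthesis, immediate early and heat shock, imprinted genes, posterior Hox genes, anterior Hox genes, extracellular matrix, germline pluripotency, meiosis, germ cell identity, and Y-linked and Xist. Some genes stand in more than 1 list or are also cell type markers, and markers of a class were left out of its lists. A list member was called higher or lower when its ratio was at least 2-fold and its interval excluded 1. A list's median log2 ratio over members with at least 10 CPM is placed as a percentile among 10000 random lists of the same size, matched on expression in bins of 25 genes. This percentile is a description of these libraries and not a test. The position of Induced D6 on genes that differ between the earliest and latest in vivo stage is 0 at the early level and 1 at the late level on the log2 scale.

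Departures from the plan were as follows. E10.5 held no separate supporting-lineage-like cluster, so the positions from E10.5 to E14.5 use the gonadal-epithelium-like class, and E11.5 to E14.5 is given for the supporting-lineage-like class. Doublets were removed at the expected rate for the reason given above. The alternatives covered the cell filter, doublets, cluster resolution and naming, fixed depth, normalization, summing of cells, the class compared, expression floor, fold threshold, reference stage, pseudocount, kind of correlation and gene set. Those added after the data were seen are the automatic Scrublet threshold, cluster names from marker share alone, the gonadal-epithelium-like class, the supporting-lineage-like scale from E11.5 to E14.5, and leaving out shared barcodes or genes shifted in every class.

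The method was tested on simulated data made from the E12.5 supporting-lineage-like class at the depths of the Induced D6 comparison, with 2599 genes of which 200 had a planted fold. At the 4-fold threshold 0 of 2399 unchanged genes, 0 of 67 genes planted at 2-fold, 67 of 67 planted at 6-fold and 66 of 66 planted at 8-fold were called. The intervals of the ratio covered the true value for 95.3% of the 2599 genes. A planted list stood at percentile 100 and an unchanged list at 39.5. Genes planted at the midpoint of the position scale gave medians of 0.500 and 0.501 in the 2 directions. Folds were planted in genes at 100 CPM or more, so the recovery of planted genes between 50 and 100 CPM was not tested. Both simulated sums were Poisson draws from the same profile. The test therefore covers counting error only, and not differences between libraries, strains or the clusters that make up a class.

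Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.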

Results

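Gene expression was measured in single cells of XX mouse gonads at 5 embryonic stages, E10.5 to E14.5, and in gonad somatic cells differentiated from mouse embryonic stem cells and collected at culture day 6 (Induced D6). There was 1 library per group and no replicate, so every interval covers counting error only. The induced cells were grown as aggregates in 3 steps of 2 days each: CHIR, BMP4 and EGF, then BMP4, retinoic acid, PD0325901, SHH and EGF, then BMP4 and FGF9. The libraries held 46494826, 41181565, 40318026, 52146419 and 37606947 UMIs from E10.5 to E14.5, and 50585914 UMIs in Induced D6. The deposited barcodes numbered 6422, 2766, 3300, 4671 and 4675 in vivo and 7564 in Induced D6. The median depth ran from 6271 UMIs per barcode in Induced D6 to 11864 at E11.5. After filtering and removal of 313, 59, 84, 167, 148 and 452 likely doublets, 5946, 2661, 3165, 4399 and 4160 in vivo cells and 7067 Induced D6 cells remained.

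Which cell types each library held was read from cluster names. Gonadal somatic cells (supporting-lineage-like, coelomic-epithelium-like and stroma-like) made up 11.05% of cells at E10.5 (10.3% to 11.9%), 69.7% at E11.5 (67.9% to 71.5%), 69.6% at E12.5 (68.0% to 71.2%), 59.6% at E13.5 (58.2% to 61.1%) and 68.0% at E14.5 (66.5% to 69.4%). In Induced D6 they were 71.4% (70.3% to 72.4%). The supporting-lineage-like class, named from genes of the pregranulosa lineage such as Fst, Wnt4 and Runx1, held 31.9% of cells at E11.5, 36.97% at E12.5, 35.6% at E13.5 and 30.2% at E14.5, against 17.7% (16.9% to 18.7%) in Induced D6. At E10.5 the class had 0 of 5946 cells, which allows a share of up to 0.0505% under the main cluster names, and 8.32% of cells lay in a cluster that carried both the supporting and the coelomic name. Such mixed clusters held 6.79%, 7.23% and 9.01% of cells at E12.5, E13.5 and E14.5. Coelomic-epithelium-like cells were 21.3% at E11.5, 13.7% at E12.5 and 33.5% (32.4% to 34.6%) in Induced D6, with 0 cells under that name at E10.5, E13.5 and E14.5. These 0 counts rest on the cluster names. Unnamed E13.5 cluster 13 (201 cells) held 6 of 14 coelomic markers, and E14.5 cluster 5 (161 cells), counted as stroma-like, held 7 of 14. At their stages they were the closest to the coelomic-epithelium-like Induced D6 clusters 5, 6 and 8 (r 0.511 to 0.605). Stroma-like cells were 2.72%, 16.5%, 12.2%, 16.8% and 28.8% from E10.5 to E14.5, and 20.15% in Induced D6. Germ-cell-like cells were 0.303%, 11.7%, 18.4%, 31.7% and 27.9% from E10.5 to E14.5. The intervals do not cover the choice of filter and clustering, which moved several of these shares further, and the order of stages in the germ-cell-like share did not hold under all of them. Endothelium-like cells were 1.95%, 1.71%, 1.77% and 1.71% from E11.5 to E14.5, and 0 of 7067 cells in Induced D6, which allows up to 0.0425%. A cluster of 19 megakaryocyte-like cells in Induced D6 (0.269%) also carried 13 of 14 endothelium markers, so endothelial cells among these are not excluded.

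Unnamed clusters held 52.2%, 11.54%, 9.29%, 5.91% and 1.13% of cells from E10.5 to E14.5 and 27.7% in Induced D6. E10.5 also held 11.8% paraxial-or-myogenic-mesoderm-like and 8.61% lateral-plate-or-limb-mesoderm-like cells. Cell cycle genes led several named clusters, among them a supporting-lineage-like cluster at E11.5, coelomic-epithelium-like clusters at E12.5 and in Induced D6, and stroma-like clusters at E14.5 and in Induced D6. The metallothioneins Mt2 and Mt3 stood among the leading genes of 2 gonadal clusters at E14.5, and the innate immune gene Pglyrp1 among those of a supporting-lineage-like cluster at each stage from E11.5 to E14.5. Embryonic haemoglobin Hbb-y led such a cluster at E14.5. The gonadal somatic difference between Induced D6 and E12.5, 1.72 percentage points, lay within counting error (-0.201 to 3.67) and ran from -1.99 to 16.5 points under other filters, doublet calls and cluster resolutions.

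**Figure D1:**
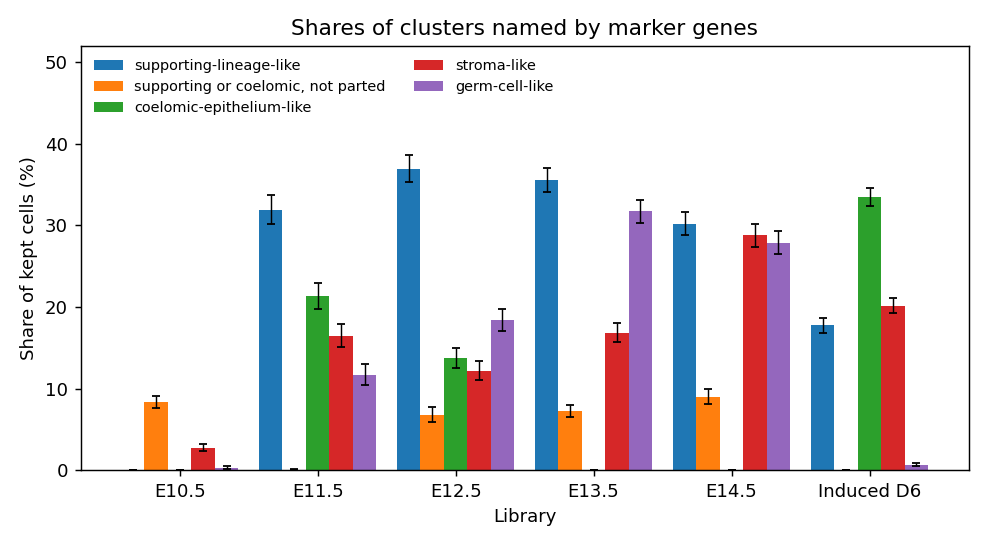
Share of kept cells in each named class, in percent, for the 6 libraries, with exact binomial 95% intervals. Supporting-lineage-like cells make up 36.97% at E12.5 and 17.7% in Induced D6.

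Whole-library levels, which do not depend on cluster names but do depend on the mix of cells, set the key genes side by side. Germ-cell-like cells made up 18.4% of cells at E12.5 and 0.651% in Induced D6, the latter in a cluster also named pluripotent-stem-cell-like. Gonadal somatic cells made up 11.05% at E10.5. Supporting-lineage-like cells made up 36.97% at E12.5 and 17.7% in Induced D6. A higher or lower whole-library level therefore does not show a higher or lower level within gonadal cells or a single class. The gonadal primordium regulators Nr5a1, Gata4 and Wt1 were higher in Induced D6 than at any in vivo stage: Nr5a1 stood at 60.7 CPM against 1.78 at E10.5 and 33.6 at E12.5, Gata4 at 129.6 against 65.4 at E12.5, and Wt1 at 747 against 222 at E12.5. Lhx9, another regulator of gonad formation, was lower, at 67.2 CPM against 332 at E11.5 and 251 at E12.5, while Emx2 stood at 139.5 against 136. Foxl2, the transcription factor that maintains granulosa identity, had 0.117, 6.46, 16.8, 49.98 and 41.9 CPM from E10.5 to E14.5 and 7.52 CPM in Induced D6. Fst stood at 264 CPM at E12.5 and 20.9 in Induced D6, Irx3 at 156 and 14.8, Kitl at 135 and 56.4, Wnt6 at 153 and 101, and Runx1 at 43.8 and 27.8. Wnt4 was higher in Induced D6, at 357 CPM against 122 at E12.5, as were Rspo1 at 112 against 88.3 and the cell cycle inhibitor Cdkn1b at 15.7 against 12.9. The stromal genes Nr2f2, Tcf21 and Pdgfra stood at 269, 163 and 31.0 CPM in Induced D6 against 121, 57.0 and 25.6 at E12.5, and the mesothelial gene Upk3b at 117 against 29.6. Sox9, which drives Sertoli cell differentiation, had 47.3 CPM in Induced D6 against 9.78 at E12.5 and 57.0 at E10.5, with Amh under 1 CPM in all libraries. The steroidogenic genes Star and Cyp11a1 stood at 30.3 and 4.85 CPM in Induced D6 against 8.30 and 7.44 at E12.5. The germ cell genes Dazl, Ddx4, Stra8 and Pou5f1 had 200.1, 30.6, 22.2 and 140.1 CPM at E12.5 and 0.196, 1.02, 0.761 and 2.80 CPM in Induced D6.

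On the GRCm38 build with GENCODE vM21 these protein-coding genes lie as follows. Nr5a1 (ENSMUSG00000026751) spans 38692656 to 38714542 on chromosome 2, minus strand. Wt1 (ENSMUSG00000016458) spans 105126529 to 105173616 on chromosome 2, plus strand. Gata4 (ENSMUSG00000021944) spans 63198922 to 63271692 on chromosome 14, minus strand. Lhx9 (ENSMUSG00000019230) spans 138825186 to 138848577 on chromosome 1, minus strand. Foxl2 (ENSMUSG00000050397) spans 98955288 to 98958543 on chromosome 9, plus strand.

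At 3000 UMIs per cell, 0.0182%, 1.64%, 5.01%, 13.1% and 10.3% of all kept cells had a Foxl2 UMI from E10.5 to E14.5, and 2.04% (1.72% to 2.40%) in Induced D6. The E12.5 interval was 4.27% to 5.83%. Thinning left out 464, 40, 50, 120, 351 and 162 cells of the 6 libraries, and the unthinned shares were 0.0673%, 5.52%, 11.8%, 23.3%, 16.9% and 3.92%. Within the supporting-lineage-like class the shares were 4.63%, 12.1%, 33.9% and 29.5% from E11.5 to E14.5 and 7.75% (6.32% to 9.38%) in Induced D6. Endothelium-like and erythroid-like cells, taken as background, showed 0.361%, 0%, 0%, 2.94% and 4.21% at median depths of 12192, 15379.5, 14775, 14844 and 9943 UMIs, where all kept cells had 6414, 11843, 10011, 9317 and 7284.5. The E10.5 share was therefore at background. Induced D6 had no such background cells, and its stroma-like class showed 0.147%.

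The in vivo libraries show how the gonadal epithelium differed across 4 days of development. In the gonadal-epithelium-like class (clusters 0 to 4 at E14.5 with 1631 cells, cluster 15 at E10.5 with 495 cells), cell cycle genes were lower at E14.5 throughout their lists. All 16 measured S phase genes and all 19 measured G2/M genes were lower, with list medians of -2.57 and -2.94 in log2. Rrm2, a subunit of ribonucleotide reductase, was 22.5-fold lower (19.6 to 26.05), the replication factor Cdc45 15.3-fold, the mitotic kinase Plk1 15.9-fold and Cdc20 15.6-fold. Hox genes were lower too: 5 of 6 anterior members (median -3.24) and 6 of 9 posterior members (median -2.51), with Hoxa5 93.5-fold lower (41.9 to 259), Hoxb2 56.1-fold and Hoxa9 89.3-fold. Retinoic acid genes were lower in 5 of 8 (median -2.63), led by the binding protein Crabp2 at 44.9-fold, with Aldh1a1 18.1-fold higher. Cholesterol synthesis was lower in 9 of 17, with Fdft1 3.87-fold lower.

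Higher at E14.5 were Wnt/beta-catenin targets, 7 of 10 (median 1.56), immediate early and heat shock genes, 10 of 15 (median 2.27), and extracellular matrix genes, 10 of 21 (median 0.96). Lgr5, a receptor for R-spondins, was at least 91.1-fold higher (0 counts at E10.5), Rnf43 43.6-fold (1 count at E10.5, 7.72 to 1732) and Sp5 7.92-fold, while the Wnt inhibitor Notum was 11.504-fold lower. Junb was 16.7-fold and Btg2 11.7-fold higher, and elastin (Eln) 46.6-fold (3 counts at E10.5, 15.9 to 227). Large single ratios included the galectin Lgals7, 1530-fold (3 counts at E10.5, 524 to 7421), Kctd14, at least 941-fold, Cst12, at least 397-fold, the metallothioneins Mt2, 268-fold, and Mt1, 126-fold, and Ifi27, 236-fold (3 counts at E10.5, 80.8 to 1147). Lower were Alx1, 456-fold (3 counts at E14.5, 155 to 2222), Ibsp, 179-fold, Nup62cl, 174-fold, Hoxa7, 146-fold, Cck, 90.0-fold, and Nr2f1, 75.8-fold. Ibsp, Nup62cl, Mt2 and Cst12 were also among the leading genes of clusters in the class, and their whole-library levels were 15.5, 11.52, 42.3 and 0.0234 CPM at E10.5 and 0.286, 3.43, 131 and 136 CPM at E14.5. Of 3400 genes, 205 were at least 4-fold higher and 307 at least 4-fold lower at E14.5, and the median of all genes was -0.53 in log2. Counted from that median, 293 were higher and 148 lower.

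Within the supporting-lineage-like class, E14.5 (clusters 0 to 3, 1256 cells) was set against E11.5 (clusters 2, 5, 8 and 15, 849 cells), the first stage with a separate cluster. The pregranulosa list was higher in 4 and lower in 2 of 8 members: Lgr5 10.4-fold (8.34 to 13.1), Irx5 5.07-fold and Cdkn1b 2.48-fold higher, and the nuclear receptor Nr0b1 5.88-fold and Msx1 3.99-fold lower. BMP targets were higher in 5 of 8, led by Id4 at 7.57-fold, and lower in 3. Extracellular matrix genes were higher in 13 of 20 (median 1.31), with Eln 13.495-fold and Col1a1 5.92-fold. Immediate early and heat shock genes were higher in 12 of 15 (median 1.69), with Atf3 28.7-fold. Glycolysis and hypoxia genes were lower in 12 of 17 (median -1.33), with Pgk1 5.91-fold lower, as were all 17 G2/M genes (median -2.56; Cdc20 12.498-fold) and 11 of 14 S phase genes (median -1.37). Cyp26b1, which degrades retinoic acid, was 38.5-fold lower. Among single genes, Mt3 was 177-fold, Pld5 73.5-fold, Cited4 69.1-fold, Adamts19 52.8-fold, Sorbs2 48.0-fold and Thbs2 34.7-fold higher. The pancreatic-type lipase genes Pnliprp2, Pnlip and Pnliprp1 were 1087-fold (2 counts at E14.5, 301 to 8978), 60.7-fold and 70.6-fold lower, Sprr2d at least 466-fold, Tgm3 440-fold (171 to 1615), Cyp11a1 156-fold, Klk1 117-fold, Utf1 61.4-fold and Siglecg 58.4-fold. Several of these led an E11.5 cluster of the class, and their whole-library levels at E11.5 and E14.5 were 79.5 and 0.343 CPM for Pnliprp2, 59.3 and 0.314 for Tgm3, and 26.9 and 0.172 for Cyp11a1. In this class 66 genes were at least 4-fold higher and 69 lower among 3096, with an all-gene median of -0.32, and counted from that median 90 were higher and 50 lower.

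In stroma-like cells at E14.5 (clusters 5, 6, 7 and 13, 1197 cells) against E11.5 (clusters 3 and 11, 438 cells), immediate early genes were higher in 9 of 15 (median 1.36), with Atf3 33.8-fold. E14.5 cluster 5, with 161 of these cells, also held 7 of 14 coelomic epithelium markers. Nfix was 27.3-fold, Eln 10.7-fold and Mgp, an inhibitor of calcification, 6.03-fold higher. Alx1 was 87.4-fold, Nefm 73.8-fold, Calb1 47.0-fold and Cck 41.4-fold lower. Calb1 and Nefm were also among the leading genes of E11.5 clusters 3 and 11. E11.5 cluster 12, with 232 cells and 15 of 19 stroma markers, was unnamed and outside the class. E14.5 cluster 13, led by cell cycle genes, was inside it. Genes and lists of this comparison with E11.5 therefore rest in part on unlike clusters. S phase genes were lower in 9 of 16 (median -1.16), extracellular matrix genes were higher in 2 and lower in 1 of 15 (median 0.20), and 1 of 4 anterior Hox genes was lower (median -0.66). Against E10.5 (cluster 8, 162 cells), Col6a2 was 268-fold (1 count at E10.5, 48.1 to 10601) and Eln 105-fold (1 count, 18.7 to 4143) higher, with extracellular matrix genes higher in 10 of 14 (median 1.92). Col9a1 was 515-fold (1 count at E14.5, 90.3 to 20566) and Foxd1 350-fold (2 counts, 94.9 to 2920) lower, and anterior Hox genes were lower in 8 of 10 (median -2.62). Foxd1 was also a leading gene of E10.5 cluster 8 and of cluster 9, whose 494 cells were left unnamed, and 1797 unnamed E10.5 cells had stroma as their best marker set, so the comparison with E10.5 rests on a small part of such cells. Over whole libraries Col6a2, Eln, Col9a1 and Foxd1 stood at 1.83, 0.866, 37.4 and 28.9 CPM at E10.5 and 57.8, 33.4, 0.257 and 0.229 CPM at E14.5. G2/M genes were lower in 19 of 19 against E10.5 (median -2.53) and higher in 16 of 19 against E11.5 (median 1.42), where a cluster led by cell cycle genes belonged to the class at E14.5 alone.

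Germ-cell-like cells at E14.5 (clusters 8, 9, 11 and 12, 1160 cells) differed from those at E11.5 (clusters 10 and 16, 311 cells) most in genes of meiosis. Meiosis genes were higher in 16 of 17 (median 5.44): Mei1 248-fold (1 count at E11.5, 44.3 to 9833), Meioc 172-fold (95.95 to 345) and the synaptonemal complex gene Sycp2 99.2-fold. Terb1, which tethers telomeres in meiosis, was 1020-fold higher (1 count at E11.5, 183 to 40322), Ankrd31 856-fold (1 count, 153 to 33829), Spdya 580-fold (2 counts, 160.4 to 4794), the recombination-site factor Prdm9 511-fold, Zfp541 397-fold (1 count, 70.95 to 15691), and the histocompatibility genes H2-D1 275-fold and H2-Ab1 at least 254-fold. Stra8, the gatekeeper of meiotic entry, stood at 1.67, 83.5, 533 and 429 CPM from E11.5 to E14.5, and Sycp3 at 37.1, 86.3, 415 and 1887. Pou5f1 stood at 735, 521, 248 and 25.2 CPM over the same stages. Single genes lower included Gdf3, 236-fold (3 counts at E14.5, 80.3 to 1150), Prdm14, 171-fold (1 count at E14.5, 30.1 to 6830), Dppa2, 113-fold, and Tcl1, 107-fold. Of the 14 germline pluripotency genes 11 were left out as class markers, and the other 3 were lower (median -2.61). Also lower were FGF/ERK targets in 8 of 11, with the other 3 higher (median -2.34; Dusp4 21.7-fold lower), glycolysis and hypoxia genes in 13 of 16 (median -2.499; Eno1 21.5-fold), cholesterol synthesis in 11 of 15 (median -1.66), S phase genes in 11 of 16 and G2/M genes in 11 of 19. Against E10.5, where the class had 18 cells, meiosis genes were higher in 14 of 17 (median 3.99) and Sox15 283-fold lower (108 to 940.2).

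Over the whole E14.5 library against E10.5, the largest ratios were germ cell genes, such as Taf7l at 9419-fold (1 count at E10.5, 1690.1 to 372092), and pregranulosa genes were higher in 14 of 18. Single genes lower included Acta1, 361-fold, Tubb3, 338-fold, and Myog, 187-fold. Acta1 and Myog were among the leading genes of the unnamed E10.5 cluster 11, with 123 cells. Neural-crest-, glia- or neuron-like cells made up 3.28% and neural-ectoderm-like cells 3.68% at E10.5, names that no later stage carried. These ratios therefore rest in part on the mix of cells. Meiosis and germ cell genes also passed the threshold in somatic classes, but Sycp3 there stood at 2.26% and 2.17% of its germ-cell-like level at E13.5 and E14.5, so these lists are not read as expression in somatic cells. The records of the E13.5 and E14.5 libraries are numbered apart from the others, the labels state no batch, and stage and batch cannot be told apart in comparisons across that step.

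The central comparison set Induced D6 against E12.5 in supporting-lineage-like cells (clusters 1 and 7 with 1254 cells; clusters 0, 3 and 5 with 1170 cells), to see how far the induced cells match their counterpart. Glycolysis and hypoxia genes were higher in Induced D6 in 12 of 19 members, with 0 lower (median 1.502, percentile 100): the prolyl hydroxylase Egln3 69.7-fold (31.6 to 191), the mitophagy receptor Bnip3 9.58-fold (8.67 to 10.6), Ndrg1 9.39-fold and the glucose transporter Slc2a1 7.73-fold. Bnip3 stood at 355 CPM, against 22.4 to 40.2 CPM over E11.5 to E14.5. FGF/ERK targets were higher in 8 of 9 (median 1.78, percentile 99.98), with Etv4 18.2-fold (8.44 to 46.5), Dusp6 7.22-fold, Etv5 6.78-fold and Spry2 3.51-fold. BMP targets were higher in 5 of 8 (median 1.53, percentile 99.98), with Id2 4.30-fold (4.05 to 4.56), Id4 3.81-fold, Smad6 3.12-fold and Id1 3.03-fold.

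Anterior Hox genes were higher in all 5 measured members (median 2.69, percentile 99.98). Hoxa5 was 61.3-fold (30.8 to 143), Hoxb4 60.1-fold (3 counts at E12.5, 20.1 to 295), Hoxc5 6.47-fold and Hoxc4 4.40-fold higher. Posterior Hox genes were higher in 1 of 3, Hoxc8 at 2.19-fold (list median 0.16). Retinoic acid genes were higher in 5 and lower in 2 of 9 (median 1.08, percentile 99.85): Cyp26b1 6.20-fold, Crabp1 4.60-fold and Dhrs3 3.75-fold higher, and Aldh1a1 2.60-fold lower. Cholesterol synthesis was higher in 5 of 17 (median 0.79, percentile 99.85), with Insig1 3.82-fold and Msmo1 3.00-fold. Primordium transcription factors were higher in 3 of 7 (median 0.67, percentile 97.0), with Tcf21 14.4-fold (10.46 to 20.3), Zfpm2 2.62-fold and Wt1 2.45-fold.

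The pregranulosa list was lower in 1 and higher in 0 of its 8 measured members (median 0.13, percentile 28.4). Among them Lgr5 was 9.78-fold lower (6.06 to 16.8), Irx5 1.93-fold lower and Cdkn1b 1.44-fold higher. The other 11 of its 19 genes, Foxl2, Fst, Wnt4 and Runx1 among them, were left out as class markers, so the median does not cover them. Over whole libraries Foxl2, Fst, Irx3, Kitl, Wnt6 and Runx1 were lower in Induced D6 than at E12.5, and Wnt4 and Rspo1 higher. The supporting-lineage-like share was 17.7% in Induced D6 and 36.97% at E12.5. These whole-library levels therefore do not show lower or higher expression within the class. Lgr5 stood at 7.03 CPM at E11.5, 73.0 at E14.5 and 2.18 in Induced D6. Sertoli genes were higher in 2 and lower in 1 of 6 (median 0.60), with Sox9 2.40-fold (1.92 to 3.00) and Cst9 3.47-fold higher and Cst8 2.83-fold lower. Steroidogenic genes were mixed, with Star 4.31-fold and Scarb1 2.40-fold higher and Cyp11a1 16.7-fold lower (9.21 to 33.9) among 6 (median 0.32). The Cyp11a1 value rests on the cluster names: the unnamed Induced D6 cluster 9, with 229 cells, had Cyp11a1 at 114 CPM and matched an E12.5 cluster of the class best (r 0.737), and over whole libraries Cyp11a1 stood at 4.85 CPM against 7.44. Wnt/beta-catenin targets were higher in 3 and lower in 2 of 9 (median 0.59), with the inhibitors Dkk1 20.4-fold and Nkd1 6.04-fold higher and Ccnd1 3.40-fold lower. S phase genes were lower in 2 of 14 (median -0.31, percentile 0.17), Uhrf1 2.17-fold and Rrm2 2.02-fold, and G2/M genes in 0 of 4 (median 0.47; Ccnb2 1.89-fold higher). Hedgehog targets were higher in 1 of 4 (Gas1, 4.53-fold; median 0.79). Imprinted genes were higher in 5 of 19 (median 0.48), with Dlk1 5.34-fold and Meg3 4.02-fold. Extracellular matrix genes were higher in 8 of 17 (median 0.40; Col1a1 4.43-fold). Immediate early and heat shock genes were higher in 5 and lower in 3 of 15 (median 0.18; Ier3 6.22-fold higher, Atf3 4.48-fold lower). The small remainder were Klf2 2.503-fold lower among 2 germline pluripotency genes, Rec8 3.10-fold higher and Tex15 2.64-fold lower among 4 meiosis genes, Taf7l 2.53-fold higher as the sole germ cell identity gene measured, and Xist 19.1-fold lower (17.6 to 20.8) as the sole gene measured of the Y-linked and Xist list.

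Among single genes, Camk2n1 was 93.2-fold higher in Induced D6 (50.4 to 195), the hypoxia-responsive repressor Bhlhe40 54.7-fold, Il11ra1, annotated as an interleukin 11 receptor subunit, 45.9-fold (33.8 to 64.0), Ndufa4l2 33.1-fold, Scrn1 27.3-fold, the growth factor Tgfb2 21.7-fold, Dusp5 17.9-fold, Smtnl2 14.9-fold and Ncam1 13.2-fold. Lower were the serpin Serpina3a, 320-fold (124.6 to 1174), Wfdc1, 72.9-fold, the homeobox gene Rhox8, 24.5-fold, Cd59a, 20.7-fold, Pglyrp1, 13.4-fold, the sphingosine phosphate receptor S1pr1, 11.6-fold, the cystatin Cst12, 11.2-fold, and Hmcn1, 7.46-fold. Serpina3a, Rhox8, Pglyrp1 and Cst12 were also among the leading genes of the E12.5 clusters, and over whole libraries stood at 80.8, 24.6, 74.9 and 41.6 CPM at E12.5 and 0.196, 1.76, 4.11 and 3.13 CPM in Induced D6. Ftl1-ps1 was 32.1-fold higher while its parent Ftl1 stood at 2667 CPM over the whole Induced D6 library and 2744 at E12.5, and Ftl1-ps1, Il11ra1 and Serpina3a have close copies in the genome, so reads shared between copies and strain variants cannot be told from expression for them.

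Of 3191 genes, 73 were at least 4-fold higher and 26 at least 4-fold lower in Induced D6, with an all-gene median of 0.23 in log2. With mitochondrial, ribosomal protein and haemoglobin genes left out of the totals the median was 0.02 and the split 82 higher and 63 lower. Relative to the median of all genes the glycolysis, FGF/ERK, BMP and anterior Hox lists stood at 1.28, 1.55, 1.31 and 2.47, and 55 genes were at least 4-fold higher and 33 lower. The extracellular matrix list stood at 0.17 relative to it and at -0.01 with clusters named by marker share alone. Across 8978 genes, Pearson's r between Induced D6 and E12.5 was 0.927, against 0.929 with E11.5, 0.903 with E13.5 and 0.883 with E14.5, and 0.981 between E11.5 and E12.5. Induced D6 against E11.5 gave 60 genes higher and 47 lower, where E12.5 against E11.5 gave 1 and 8. The strain differs between Induced D6 and the in vivo libraries, so strain and origin cannot be told apart for any gene of this comparison.

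**Figure D2:**
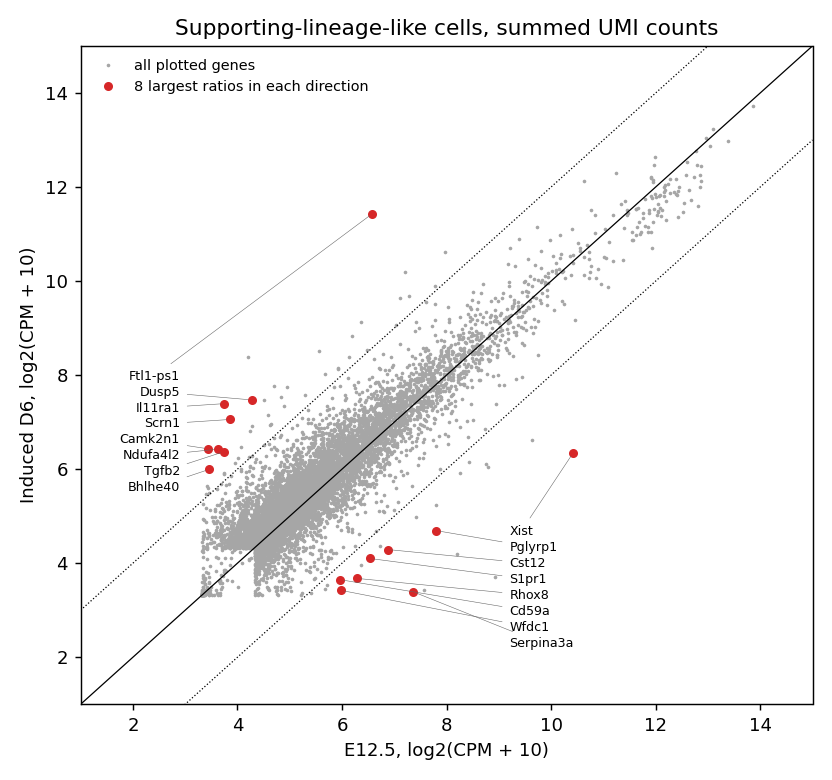
Log2 of CPM with 10 added for each gene in summed supporting-lineage-like cells, Induced D6 against E12.5, with the 8 largest ratios in each direction labelled. Before that addition Camk2n1 is 93.2-fold higher and Serpina3a 320-fold lower in Induced D6.

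**Figure D3:**
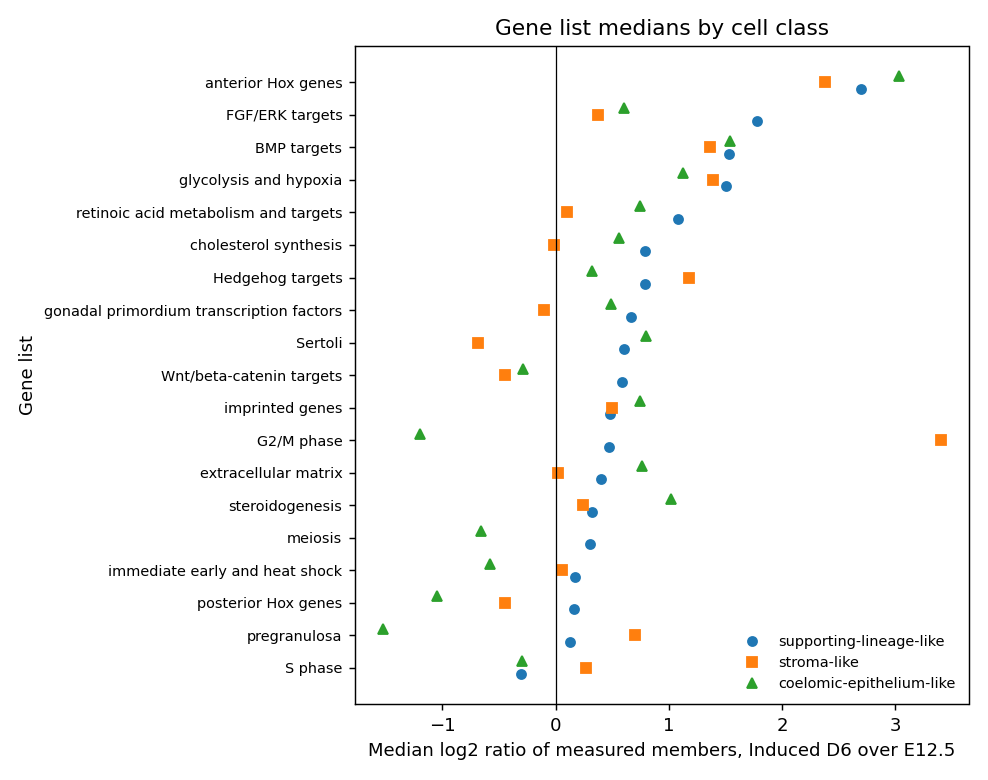
Median log2 ratio of Induced D6 to E12.5 over the measured members of each gene list, in supporting-lineage-like, stroma-like and coelomic-epithelium-like cells. Anterior Hox genes have the highest median in supporting-lineage-like cells, 2.69, over 5 measured members.

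In stroma-like cells (clusters 3 and 10 with 1424 cells in Induced D6; clusters 2 and 8 with 385 cells at E12.5) several of the same groups were higher in Induced D6. All 11 measured anterior Hox genes were higher (median 2.37, percentile 100), with Hoxb2 60.3-fold (3 counts at E12.5, 20.5 to 294) and Hoxb5 23.7-fold (10.1 to 73.4). Posterior Hox genes were higher in 2 and lower in 3 of 8, with Hoxd10 at least 97.0-fold and Hoxc10 84.2-fold (3 counts in Induced D6, 27.9 to 417) lower. Glycolysis and hypoxia genes were higher in 14 of 19 (median 1.39, percentile 100), with Bnip3 13.4-fold (10.2 to 17.8) and Slc2a1 7.16-fold. BMP targets were higher in 6 of 9 (median 1.37, percentile 99.99), with Gata2 6.61-fold and Id3 3.72-fold. Hedgehog targets were higher in 2 of 4 (Gas1 4.65-fold, Boc 3.72-fold), FGF/ERK targets in 2 of 11 with 1 lower (median 0.37, percentile 82.5), and retinoic acid genes in 4 of 9 with 1 lower (median 0.10, percentile 26.6), Cyp26b1 being 13.7-fold higher (3 counts at E12.5, 4.59 to 67.5). Among primordium transcription factors Osr1 was 7.09-fold and Wt1 2.37-fold higher and Lhx9 12.4-fold lower (10.1 to 15.2). The potassium channel gene Kcnj8 was 181-fold (1 count at E12.5, 32.3 to 7150), Il11ra1 37.1-fold, Slc16a6 34.3-fold and Lrrn2 23.9-fold higher. The calcium-binding protein gene Calb1 was 134-fold (80.4 to 240.1), Cpa1 26.9-fold, the creatine synthesis enzyme Gatm 23.8-fold, Tulp2 17.7-fold and Ass1 10.9-fold lower. Over whole libraries Calb1 stood at 32.5 CPM at E12.5 and 2.48 in Induced D6. Calb1 led E12.5 cluster 2, which held 254 of the 385 cells, and the Induced D6 clusters that matched it, 2 (r 0.739) and 4 (r 0.636), were unnamed and outside the class. Induced D6 cluster 10 matched the unnamed E12.5 cluster 1 best (r 0.755), so every gene and list of this comparison rests in part on unlike clusters.

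The stroma-like comparison gave 108 genes at least 4-fold higher and 25 lower among 3361, and r 0.917 across 9324 genes, against 0.928 with E11.5 and 0.922 with E13.5. G2/M genes were higher in 19 of 19 (median 3.40; Ccnb1 25.2-fold) with the main cluster names and had a median of -0.14 with clusters named by marker share alone (1882 and 568 cells), so this list rests on which cycling cluster was given the name. The glycolysis, BMP and anterior Hox medians were 1.62, 1.39 and 2.73 under that naming.

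Where Induced D6 lies between the earliest and latest in vivo stage was read from genes chosen in the in vivo libraries alone. The gonadal-epithelium-like class differed in make-up between libraries. Clusters named coelomic-epithelium-like held 2365 of its 3619 cells in Induced D6, 434 of 1819 at E12.5 and 0 of 1631 at E14.5. Clusters that carried both names held all 495 cells at E10.5, 215 at E12.5, 375 at E14.5 and 0 in Induced D6. The E14.5 cluster of this kind had Upk3b among its leading genes, so coelomic cells at E14.5 are not excluded. Positions in this class therefore mix its make-up with stage. On the 205 genes higher at E14.5 than at E10.5 in gonadal-epithelium-like cells, the median position was 0.705 at E11.5, 0.758 at E12.5, 0.952 at E13.5 and 0.595 in Induced D6 (quartiles 0.342 to 0.816). Of these genes 128 lay past the midpoint in Induced D6 and 17 below the E10.5 level. On the 307 genes lower at E14.5, the median was 0.379 at E11.5, 0.486 at E12.5, 0.956 at E13.5 and 0.453 in Induced D6 (quartiles 0.312 to 0.584), with 120 genes past the midpoint. Lgals7 stood at 467 CPM in Induced D6, between 0.804 at E10.5 and 1230.0 at E14.5, and Rrm2 at 66.6 CPM, near its E12.5 level of 59.5. Hoxa5 stood at 62.1 CPM, above its E10.5 level of 40.2, and Lgr5 at 2.73 CPM against 17.7 at E12.5.

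Within supporting-lineage-like cells, on the scale from E11.5 to E14.5, the 66 genes higher at E14.5 had a median of 0.278 in Induced D6 (quartiles -0.157 to 0.579) and 0.274 at E12.5. The 69 genes lower at E14.5 had 0.430 in Induced D6 and 0.326 at E12.5. In stroma-like cells from E10.5 to E14.5 the medians in Induced D6 were 0.890 for 151 higher genes and 0.591 for 152 lower genes, and from E11.5 to E14.5 they were 0.601 (quartiles 0.0732 to 1.07) for 32 higher genes and 0.456 for 41 lower genes. The position on higher genes depends on the stages that set the scale. In gonadal-epithelium-like cells it was 0.0444 in Induced D6 from E11.5 to E13.5, against 0.595 from E10.5 to E14.5.

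**Figure D4:**
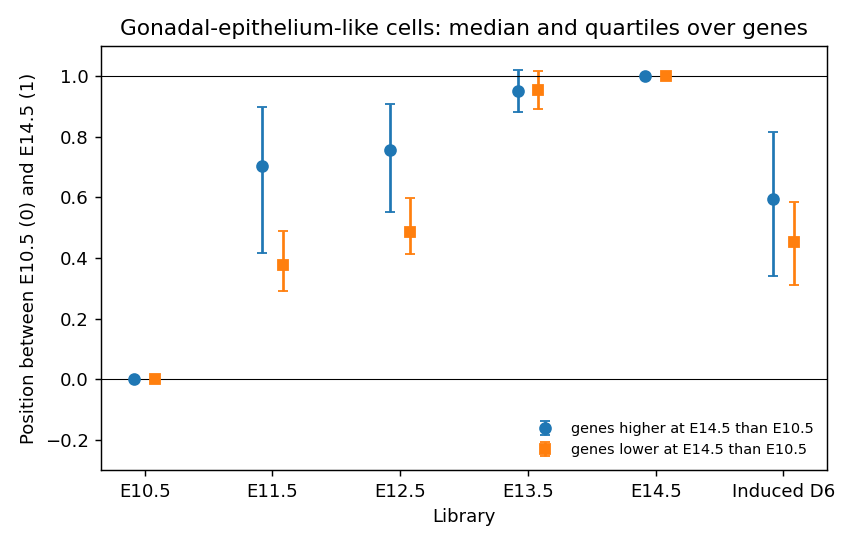
Median position with quartiles of each library between E10.5 (0) and E14.5 (1), for genes higher and lower at E14.5 in gonadal-epithelium-like cells. Induced D6 lies at 0.595 for higher and 0.453 for lower genes, and E13.5 at 0.952 and 0.956.

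Xist (ENSMUSG00000086503), the lincRNA that silences the X chromosome from which it is expressed, spans 103460366 to 103483254 on the minus strand of chromosome X. It stood at 1068, 783, 924, 1357 and 1789 CPM from E10.5 to E14.5 and at 83.1 CPM in Induced D6. At 3000 UMIs, 75.7% of E12.5 cells (74.2% to 77.2%) and 5.24% of Induced D6 cells (4.73% to 5.79%) had a Xist UMI, and the unthinned shares were 80.7% and 5.59%. In supporting-lineage-like cells the shares were 94.1% and 5.08%. Germ-cell-like cells, which reactivate the X chromosome, showed 1.77% at E12.5 at a median depth of 17168 UMIs, against 9169 UMIs in supporting-lineage-like cells.

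**Figure D5:**
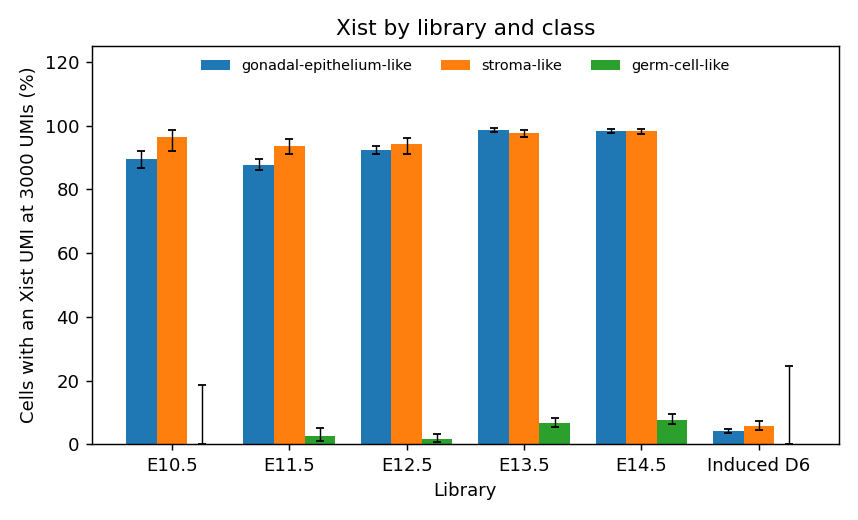
Share of cells with a Xist UMI at 3000 UMIs per cell, in percent with exact binomial 95% intervals, by library and class. Gonadal-epithelium-like cells show 92.3% at E12.5 and 4.22% in Induced D6.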

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

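All 3 tests of this part were chosen only after the result was seen. In the E13.5 and E14.5 libraries, 64 barcodes with at least 5 UMIs of Cd74, Tbata, Prss16 and H2-Aa, genes of thymic epithelium and antigen presentation, were present in both libraries. Separate cells of this type in each dissected tissue would share barcodes no more often than other cells do, yet 90.8% of such E13.5 barcodes were also in E14.5, against 0.979% of all other E13.5 barcodes. Molecules passed between these libraries alone would need a deep source in 1 of them, and the median depth of such barcodes was at most 0.150 of the library median. Molecules of another library read into both fit these values, a source that the deposited files cannot name.

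Induced D6 held 46 cells in a cluster named germ-cell-like or pluripotent-stem-cell-like, cluster 13, with Pou5f1 at 417 CPM and Stra8 at 168 CPM. Its best marker set was pluripotent stem cell, with 6 of 11 markers. Of the germ cell genes, Dppa3 stood at 122, Sycp3 at 35.6 and Dazl at 5.09 CPM, and Ddx4, Tex101 and Syce3 at 0. The values do not tell which of the 2 names holds. The median depth of the cluster was 2016 UMIs, 0.326 of the library median, and no test of the origin of these cells was made. No cluster took this name at cluster resolution 0.5, and the share of such cells was 0.0945% with the stricter cell filter.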

How the results depend on the processing

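Each main result was recomputed under other settings. Of 115 alternatives for the comparisons, 77 stayed in range and 38 moved out of it. The range was the 95% counting interval for a difference in shares, 0.02 for a correlation, 1.5 times for a count of genes and, for a position, the middle 95% of medians over resampled genes. No difference whose interval excluded 0 changed sign. For the moved values below the cause was not tested unless stated. The automatic Scrublet threshold, cluster names from marker share alone, the gonadal-epithelium-like class, the supporting-lineage-like scale from E11.5 to E14.5, and leaving out shared barcodes or the 26 genes shifted in every class were chosen after the data were seen.

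The difference in gonadal somatic share between Induced D6 and E12.5, 1.72 percentage points, has an interval that includes 0 and changed sign under some settings: it was -0.440 without a cell filter, 12.8 with a stricter filter, 14.1 with doublets kept, -1.99 at cluster resolution 0.5, 16.5 at resolution 2 and 8.32 with the automatic Scrublet threshold. The supporting-lineage-like difference, -19.2 points, was -23.8 and -14.8 at resolutions 0.5 and 2 and -16.0 with the automatic threshold. The shares of single libraries depended more on these settings: 67 alternatives stayed in range and 59 moved. At E10.5 the gonadal somatic share, 11.05%, ran from 7.78% to 23.4% and left its range under every alternative, and the supporting-lineage-like share, 0%, was 8.43% at resolution 0.5. The supporting-lineage-like share ran from 22.7% to 43.5% at E13.5 and from 0% to 39.4% at E14.5, where the stricter filter left no cluster of that name. The germ-cell-like share at E13.5, 31.7%, was 12.4% at resolution 0.5, under the E12.5 share, and 39.6% with the stricter filter, and at E14.5 it ran from 27.7% to 40.6%.

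The Foxl2 difference, -2.97 points, was -4.95 at 5000 UMIs and -7.93 without thinning, which by construction counts more molecules in the deeper library.

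Genes at least 4-fold higher in Induced D6 than E12.5 supporting-lineage-like cells, 73, became 238 at a floor of 10 CPM, 21 at 200 CPM and 365 at 2-fold. The 26 lower genes became 124 and 7 at those floors and 114 at 2-fold, each a change that follows from the threshold itself. The lower count was also 63 with mitochondrial, ribosomal protein and haemoglobin genes left out of the totals, 43 over whole libraries, and 47 against either E11.5 or E13.5. The correlation of 0.927 was 0.904 over whole libraries, 0.893 and 0.952 with pseudocounts of 1 and 100, 0.876 by Spearman's method and 0.903 on the 2000 most variable genes.

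The position on genes higher at E14.5, 0.595, was 0.715 with the stricter filter, 0.338 over whole libraries, 0.0444 from E11.5 to E13.5 and 0.278 from E11.5 to E14.5 in supporting-lineage-like cells. The position on genes lower at E14.5, 0.453, was 0.481 without a filter, 0.580 with the stricter filter, 0.536 at resolution 0.5, 0.527 with the reduced totals, 0.498 with median-of-ratios scaling, 0.536 over whole libraries, 0.383 at 2-fold and 0.280 from E11.5 to E13.5.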

Other observations

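Of the tests in this part, those of the Y chromosome, of genes that escape silencing, of a few genes shifted in every cell type, and of how many germ cell genes could reach the floor were chosen only after the result was seen. Coelomic-epithelium-like cells of Induced D6 (clusters 0, 5, 6 and 8, 2365 cells) were set against those of E12.5 (clusters 4 and 9, 434 cells). Pregranulosa genes were lower in 9 and higher in 2 of 16 (median -1.52): the activin antagonist Fst 23.0-fold (12.6 to 46.0), Wnt6 12.2-fold, Gng13 11.2-fold and Irx3 9.95-fold lower. Sox9 was 9.01-fold higher (6.54 to 12.7) and Cst8 60.3-fold lower. Anterior Hox genes were higher in 7 of 8 (median 3.04), with Hoxa3 40.3-fold (15.6 to 148), and posterior Hox genes lower in 4 of 7. BMP targets were higher in 7 of 11, with Gata2 8.001-fold, glycolysis and hypoxia genes in 13 of 19, with Ndrg1 21.1-fold, and FGF/ERK targets in 3 of 9. Il11ra1 was 58.3-fold, Angptl7 41.7-fold and Hic1 30.7-fold higher, and Serpina3a at least 614-fold lower. A cycling cluster, 4, made up 344 of the 434 E12.5 cells, while the large Induced D6 clusters 5 and 6 matched E12.5 cluster 9, with 90 cells (r 0.725 and 0.665), better than cluster 4 (r 0.347 and 0.219). Unlike clusters are thus compared for every gene and list of this paragraph, and cell cycle genes are not read.

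An unnamed Induced D6 cluster of 767 cells, cluster 12, was led by Notum, Pax8, Tbx1 and Egfl6, with Pax8 at 326 CPM, and its best marker sets were mesonephric tubule and duct, 4 of 14, and supporting lineage, 3 of 15. Its closest in vivo clusters were also unnamed: cluster 7 at E11.5 with 75 cells (r 0.752) and cluster 6 at E12.5 with 111 cells (r 0.755), where Pax8 stood at 139 CPM. The marker set with the largest share in both in vivo clusters was supporting lineage, with 7 and 8 of 15 markers, and the closest clusters at E13.5 and E14.5 were supporting-lineage-like at lower r (0.512 and 0.475). Another unnamed cluster of 229 cells, cluster 9, carried the steroidogenic genes Cyp11a1 at 114 CPM and Star at 109 CPM. The clusters and genes of this paragraph were chosen after their values were seen.

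Xist was low in Induced D6. The genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0 CPM, which leaves no sign of a Y chromosome. Xist UMIs per positive supporting-lineage-like cell were 0.910 of those at E12.5, so a strain difference that lowers reads in every cell does not account for it. Between Xist-negative and Xist-positive gonadal somatic cells of Induced D6, X-linked genes stood at -0.0849 relative to autosomal genes in log2, which argues against 2 active X chromosomes and leaves 1 X chromosome open. The median of 4 genes that escape silencing was -0.335, but the interval of the ratio excluded 1 for Eif2s3x alone, and karyotype is not given in the sources used here.

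On genes lower at E14.5 in gonadal-epithelium-like cells the median position was 0.379 at E11.5, 0.486 at E12.5 and 0.956 at E13.5. On scales from E10.5, this step from E12.5 to E13.5 was not the widest on genes higher at E14.5 or in stroma-like cells. On scales from E11.5 to E14.5 it was the widest for higher and for lower genes, in supporting-lineage-like and in stroma-like cells. Between E12.5 and E13.5 the medians went from 0.274 to 0.804 (higher) and 0.326 to 0.830 (lower) in supporting-lineage-like cells. In stroma-like cells they went from 0.173 to 0.803 and 0.242 to 0.841. Without cycling-linked genes the difference in gonadal-epithelium-like cells on genes lower at E14.5 was 0.488, so fewer cycling cells do not account for the step there. The correlation of E13.5 to E12.5 ratios between stroma-like and germ-cell-like cells was 0.416, against 0.472 at the step before and 0.241 at the step after. This left a shift of whole libraries undecided. Over all 6 pairs of classes the range was 0.382 to 0.764, with 4 pairs above 0.5. The range was 0.453 to 0.609 at the step before and 0.241 to 0.690 at the step after. RNA of germ cells in other droplets is also left open: 0% of the genes at least 4-fold higher in E13.5 supporting-lineage-like cells were germ cell genes, but at the 2.22% level of such RNA only 1 gene could have reached the 50 CPM floor. In all 4 classes 26 genes were at least 2-fold higher or lower, against 6 and 5 at the steps before and after, which is consistent with a difference in preparation, sequencing or counting for these genes.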
